A study of Mus musculus with 12 samples.

How the data were processed

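The series holds 12 RNA-seq libraries of satellite cells, the muscle stem cells, isolated from mouse hindlimb muscle 3 days after injury. Muscles were injured with 50 µl of 1.2% barium chloride spread over about 20 sites. The labels give 4 groups of 3 libraries: wild type and Hoxa9 knockout, each from young animals of 3 to 4 months and old animals of 22 to 28 months. The labels number the libraries 1 to 3 in each group and do not say whether a library came from 1 animal, so p-values measure the spread between these samples.

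Each deposited file holds whole-number read counts per gene symbol for 1 library, not normalized. Per the submitters' processing notes, TopHat and HTSeq were used, DESeq2 was named and the genome build was mm9, without versions. The labels' protocols name a stranded total RNA kit with removal of ribosomal RNA. Whether the authors counted by strand, and how they treated reads that align to several genes beyond the summary lines of the counter, is not given in the sources used here. Overlapping and antisense genes, histone genes and globin genes can therefore share reads, and their values are uncertain. The summary lines that name no gene stayed out of library sizes and tests. Reads outside any gene made up 32.2% to 70.8% of uniquely aligned reads, and ambiguous reads 0.433% to 1.37%.

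The files list 22310 gene symbols. Reads counted in genes ranged from 4193433 to 20337015 per library. Genes with low counts were removed with the filterByExpr function of edgeR, which left 13540. Counts were scaled with trimmed-mean factors and fitted with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust fit, 1 mean per group over all 12 libraries). Adjusted p-values are Benjamini-Hochberg values over all tested genes of a comparison, with 0.05 as the threshold. Levels are CPM, gene counts relative to library size after those factors, as mean ± SD of 3 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Old minus young, knockout minus wild type and, for the interaction, the age effect in knockout minus that in wild type set the signs. A fold against a group at 0 in all libraries is a lower bound, the mean of the other group against 3 counts over that group. Floors and intervals cover counting error only.

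Before the data were examined, 27 gene lists were written, 25 of them for testing and 2 as checks of sex-linked and housekeeping genes. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance one way. List p-values are adjusted over the 25 lists. The rule for named genes was also set then: Hoxa9, the 10 largest changes in each direction for the first 2 comparisons and 5 for the others, among genes past the threshold with a mean log2 CPM over 1 and no overlap between the groups. Where a direction had fewer than 5, the smallest p-values filled it, stated as not past the threshold. Up to 4 members of each list past the threshold could be named, or else up to 2 of the most abundant as values. Chance gives no overlap in 10% of genes for 3 libraries against 3.

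Alternatives set beforehand were DESeq2 1.42.0, limma-voom with and without sample weights, other scaling factors, other filters, fits of only the groups compared, a replicate block, 1 surrogate variable (sva 3.50.0), a 2-fold minimum and leaving out each library. Chosen after seeing the data were offsets for GC content and length, and fits without the 2 old knockout libraries with male levels of Y-linked reads or without 2 libraries with many reads outside genes. A choroid plexus list, a tendon list and a set of macrophage genes outside the fixed list were written after the leading genes had been seen. GC content and length came from GENCODE M21, another build than mm9, so no coordinates are given; 92.3% of symbols matched. No library repeated another: Spearman correlations over genes were 0.962 to 0.981 within groups and 0.946 to 0.977 between groups.

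The code was tested on simulated data with 200 changed genes. Of 67 genes changed 2-fold, the fit recovered 56.7% for ageing in wild type (13231 genes), 61.2% for knockout in old mice (13251 genes), 56.7% for knockout in young mice (13225 genes), 55.2% for ageing in knockout (13252 genes) and 14.9% for the interaction (13213 genes). False calls made up 8.04%, 5.36%, 3.54%, 10.6% and 0% of the calls in that order, 3 of them above the threshold of 0.05. For 4-fold changes the interaction recovered 75.8% of 66 genes. A GC trend put into the wild-type libraries, with no gene changed, gave 4534 calls for knockout in old mice among 13252 genes and 0 with GC offsets. That trend was built from the same GC values that the offsets use. The 0 therefore checks the code and not whether the offsets remove all of the trend in the data. To judge the pair of comparisons that share the old wild-type libraries, counts were also simulated with no change, with ageing as fitted, and, added later, with ageing and knockout effects scaled to the variance left after their squared SE in 10 expression bins, the knockout effects shuffled among genes of a bin. Figures were drawn with matplotlib 3.10.9.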

Results

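Satellite cells activated by muscle injury were profiled by RNA-seq in wild-type and Hoxa9 knockout mice, young and old, to ask how ageing changes their transcripts and whether loss of Hoxa9, a homeobox transcription factor, alters that change. Each of the 4 groups held 3 libraries. Reads counted in genes were 20337015, 6125999 and 12151724 in young wild type, 14938635, 9039861 and 13601348 in old wild type, 11874897, 8347030 and 4193433 in young knockout, and 6923987, 14713194 and 4453886 in old knockout.

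Hoxa9 itself stood at 10.3 ± 2.01 CPM in young wild type and 17.6 ± 4.27 CPM in old wild type (SD, n = 3). It stood at 6.40 ± 0.848 CPM in young knockout and 5.80 ± 1.08 CPM in old knockout. In old mice it was lower in knockout, with a log2 fold change of -1.63 ± 0.25 (SE) and an adjusted p of 0.00235 in edgeR's quasi-likelihood test. Without the 2 old knockout libraries with male levels of Y-linked reads, which leaves 1 library in that group, the log2 fold change was -1.44. Its change with age in wild type, 0.79 ± 0.23, did not pass the threshold (adjusted p = 0.123), nor did the difference between genotypes in young mice, -0.67 ± 0.24 (adjusted p = 0.0671). Between 22 and 87 Hoxa9 reads remained in each knockout library. The labels do not state which part of the gene was deleted, so these reads check the labels only in part.

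**Figure D1:**
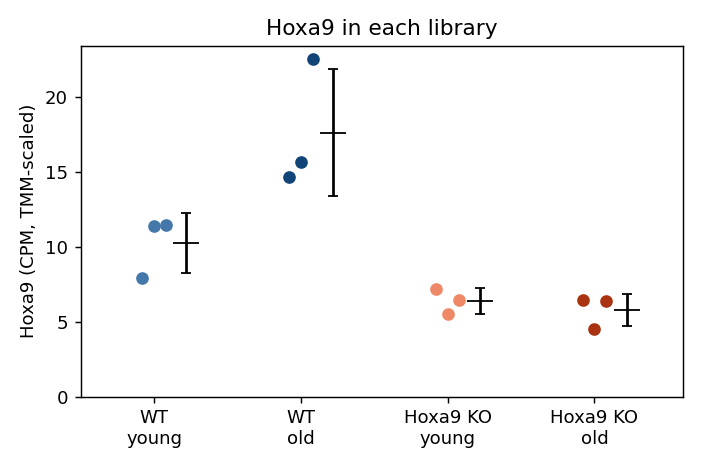
Hoxa9 in each library in CPM (vertical axis) by group (horizontal axis); points are libraries, and the line with bars is the mean ± SD of 3 libraries. All knockout libraries lie between 4.55 and 7.21 CPM, and old wild type lies between 14.7 and 22.5 CPM.

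The libraries of the 2 genotypes also differed in ways that bear on every comparison between them. Across genes, the relative level rose with GC content in all 6 wild-type libraries (Spearman's rho 0.224 to 0.488) and fell with it in all 6 knockout libraries (rho -0.534 to -0.134). Genes are not independent replicates, so no p-value is given. Lars2, the mitochondrial leucyl-tRNA synthetase, took 0.0258% to 0.11% of gene counts in wild type and 0.484% to 25.0% in knockout. Its share was largest, at 25.0% and 8.92%, in old knockout replicate 3 and young knockout replicate 2. These 2 libraries also held the most reads with several alignments, 7.54 and 3.49 per gene read. In wild type such reads numbered 1.69 to 3.22 per gene read without a large Lars2 share. Whether the reads counted for Lars2 come from its own transcript was not tested. Ttr, the transthyretin gene that choroid plexus and liver express strongly, was found at 70.7 to 4260 CPM in the wild-type libraries and at 0 in all 6 knockout libraries. Y-linked reads marked old knockout replicates 2 and 3 as male, with Ddx3y at 93.6 ± 77.7 CPM in that group against 2.15 CPM or less on average in the others. Old wild-type replicate 2 detected 20282 genes, against 14795 to 16711 in the other libraries, and 57.1% of its uniquely aligned reads lay outside genes. That share was 70.8% in old knockout replicate 3. It was 48.6% in old knockout replicate 1, 51.0% and 52.5% in young knockout replicates 1 and 2, and 32.2% to 40.8% in the others. The 2 libraries left out below for many reads outside genes are thus the highest of a graded range.

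**Figure D2:**
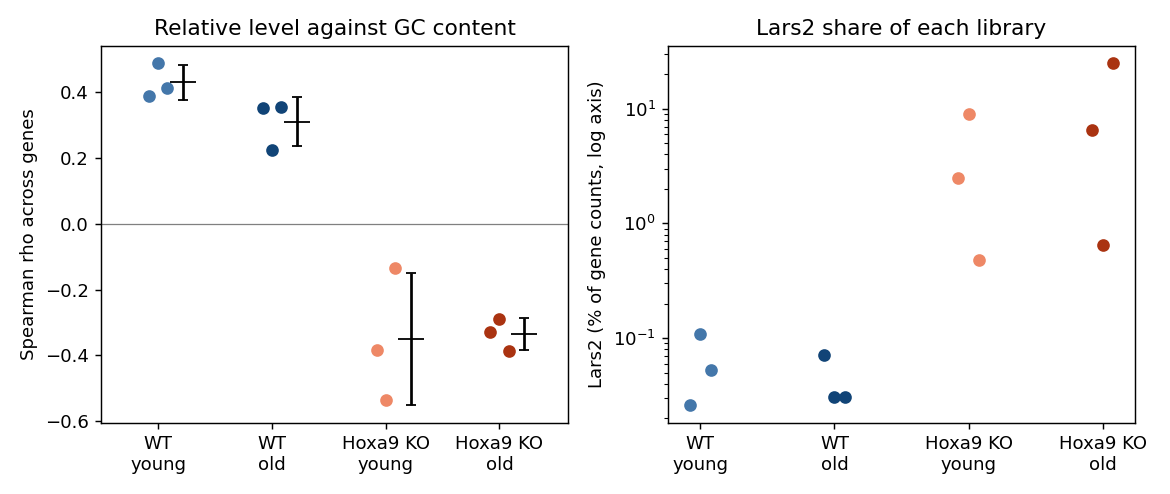
Left, Spearman's rho across genes between relative level and GC content for each library, with mean ± SD per group; right, the Lars2 share of gene counts in percent on a log axis, 1 point per library. Wild-type libraries lie above 0 and knockout libraries below 0 on the left, and every knockout library holds a larger Lars2 share than every wild-type library on the right.

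Ageing in wild type lowered 12 of 45 extracellular matrix genes in the satellite cell fraction and raised 35 genes in all, among them Il1b and Tnf. Col4a1 and Col4a2, which form the basement membrane collagen network, fell from 2095 ± 299 to 829 ± 56.4 CPM and from 1347 ± 245 to 563 ± 47.4 CPM. Pax7, the transcription factor that marks satellite cells, fell from 366 ± 31.9 to 221 ± 20.3 CPM (log2 fold change -0.72 ± 0.14, adjusted p = 0.0271). Il1b, a pro-inflammatory cytokine, rose from 0.974 ± 0.328 to 10.4 ± 0.955 CPM (3.33 ± 0.47, adjusted p = 0.00644), and Tnf rose by 2.85 ± 0.45. Macrophage and monocyte markers had positive values too (median 1.67, 0 of 25 past the threshold). Whether Il1b and Tnf rose within satellite cells was not tested. In all, 144 of 13540 genes changed, 35 higher and 109 lower in old mice.

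Among the genes with a mean log2 CPM over 1, which leaves out Tnf, the largest rises after Il1b were in Slc7a11 (log2 fold change 2.33), the cystine transporter, and Col4a6 (1.56), a further basement membrane collagen. Mmp19 (1.55), a matrix metalloproteinase, Zfp52 (1.51) and Nrcam (1.46), a neuronal-type adhesion molecule, followed. Polr3g (1.39), a subunit of RNA polymerase III, Slc9a2 (1.29), a sodium-proton exchanger, Prrg4 (1.23) and Zfp82 (1.18) completed the 10. The largest falls were in Col22a1 (-3.58), a collagen of the myotendinous junction, Col15a1 (-2.72), Kcnj8 (-2.71), a potassium channel found in pericytes, and Gpc3 (-2.62), a heparan sulphate proteoglycan. Stc1 (-2.51), Ctnna2 (-2.24), Fibin (-2.21), Cd248 (-2.16), Tril (-1.99) and C530008M17Rik (-1.92) also fell.

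Of 45 measured extracellular matrix genes, 0 rose, 12 fell and 33 did not pass, and 23 fell when adjusted over the list alone. Col6a2 (-1.18) and Col15a1 were among them, the list's median was -0.69, and camera gave an adjusted p of 2.38e-19 (adjusted p = 0.163 with an estimated correlation). Fry gave an adjusted p of 0.0084 for the matrix list. The mean over the list was lower in each of the 3 old than in each of the 3 young wild-type libraries. Among 27 genes of satellite cell identity and quiescence, 3 fell (7 adjusted over the list alone): Pax7, Heyl (-0.81), a Notch effector, and Fgfr4 (-0.77). Camera gave 6.80e-05 for that list (adjusted p = 0.215 with an estimated correlation and 0.0311 with fry). In the Notch list 1 of 26 genes fell, Heyl (3 adjusted over the list alone), and 18 had negative values (median -0.16, camera adjusted p = 0.0207, adjusted p = 0.314 with an estimated correlation and 0.0311 with fry). In the immediate early list 1 of 34 genes fell, Egr2 (-1.43), a growth-factor-induced transcription factor (camera 4.41e-06, adjusted p = 0.646 with an estimated correlation). One gene each fell in the Wnt list (Vangl2, -0.74, of 54), the TGF-beta and BMP list (Fstl1, -0.80, of 54) and the interferon list (Stat2, -0.82, of 38). Their camera adjusted p-values were 0.00191, 0.00189 and 0.00233 (adjusted p = 0.314, 0.405 and 0.664 with an estimated correlation). Without young replicate 1 the Notch and Wnt lists no longer passed camera (0.0822 and 0.0536) and the interferon median was -0.15, and the Notch median was -0.09 without old replicate 1 and -0.04 without young replicate 2. The mature myofibre list had a camera adjusted p of 0.00189 upward with none of 24 genes past the threshold (adjusted p = 0.744 with an estimated correlation).

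Markers of other cell types moved as well. In the fibroblast and fibro-adipogenic list 3 of 23 genes fell, Cd248, Col1a1 (-1.71) and Col3a1 (-0.74), with a camera adjusted p of 0.00155 (adjusted p = 0.366 with an estimated correlation). In the pericyte and smooth muscle list 1 of 17 fell, Kcnj8 (9 adjusted over the list alone, camera 1.94e-05, adjusted p = 0.366 with an estimated correlation). All 25 macrophage and monocyte markers had positive values, with a median of 1.67, and 0 passed over all genes while 6 passed when adjusted over the list alone (camera 1.33e-15, adjusted p = 0.314 with an estimated correlation). Lyz2 stood at 11.1 ± 2.62 CPM in young and 47.3 ± 2.02 CPM in old wild type. Among 46 senescence and secretory genes 3 rose and 2 fell, including Igfbp3 (-1.44) and Mmp2 (-1.20), and camera gave 0.821. In the differentiation list 1 of 39 genes fell, Cdkn1c (-0.92), the cell cycle inhibitor p57, and in the JAK-STAT list 1 of 53 fell, again Stat2. No gene passed among 10 Hoxa, 11 other Hox, 39 cell cycle, 54 histone, 40 Trithorax and Polycomb, 61 respiratory chain, 8 neutrophil, 1 lymphocyte, 17 endothelial, 16 Schwann and neural, 6 erythroid, 5 sex-linked or 14 housekeeping genes. The count depended on single libraries: leaving out 1 at a time gave 6 (without old replicate 3) to 73 (without young replicate 2), 23 without old replicate 2, and 2 without the 2 libraries with many reads outside genes. Of 36 genes past the threshold that the naming rule covers, 14 to 30 did not pass without 1 library and 34 without those 2. DESeq2 called 156 higher and 304 lower, library size alone gave 30 higher and 53 lower, and offsets for GC content and length gave 62 higher and 118 lower.

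**Figure D3:**
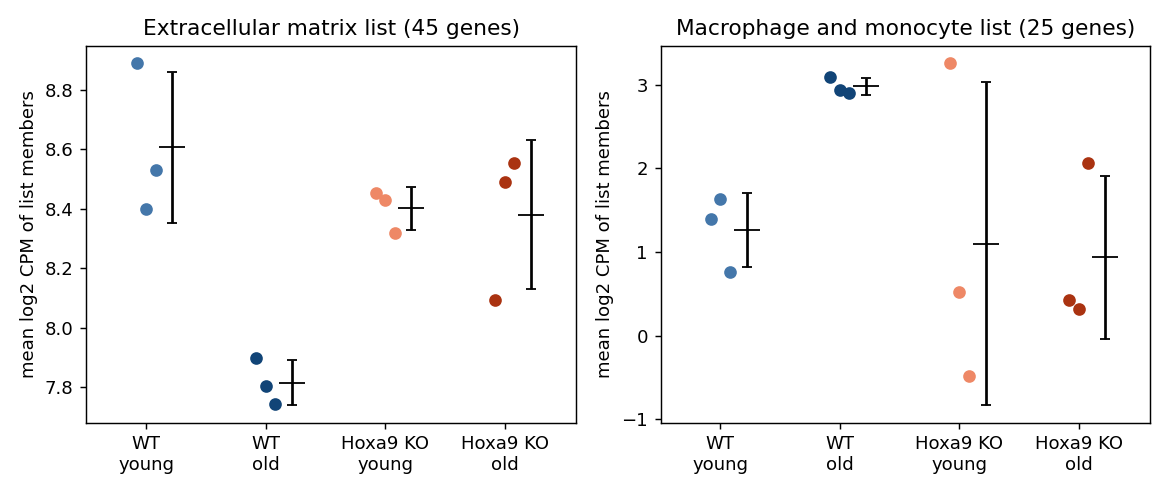
Mean log2 CPM of the extracellular matrix list (left) and the macrophage and monocyte list (right) in each library, by group; points are libraries, and lines with bars are mean ± SD of 3 libraries. Old wild type lies lowest for the matrix list, and the axes do not start at 0.

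Knockout in old mice was set against old wild type to see which transcripts Hoxa9 loss changed at that age. Of 39 genes of muscle differentiation 8 were lower in knockout, and of 24 genes of a tendon list 19 were higher. The tendon list was written after the leading genes had been seen. Of its 15 members not seen before, 10 were higher. Mef2d, a myogenic transcription factor, fell from 167 ± 2.08 to 58.7 ± 7.29 CPM (log2 fold change -1.5 ± 0.14, adjusted p = 0.000489), and the troponins Tnni1, Tnnt2 and Tnnt1 fell by 1.59, 1.25 and 1.01. Il1b, raised with age in wild type, was lower in old knockout, with a log2 fold change of -3.84 ± 0.52 (adjusted p = 0.00158), at 0.769 ± 0.203 CPM. Macrophage markers were lower there too (median -2.10, 6 of 25 past the threshold). In all, 2265 of 13540 genes changed (16.7%), 1289 higher and 976 lower.

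Among genes with a mean log2 CPM over 1 and no overlap between the groups, the largest rises were in Lars2 (8.36) and the Y-linked Ddx3y (6.41). The 8 further genes were Kera (6.40), a keratan sulphate proteoglycan, Angptl7 (5.66), Comp (5.19), a cartilage and tendon matrix protein, and Tnmd (5.18), a tendon marker. Fmod (4.61), a collagen-binding proteoglycan, Thbs4 (4.38), Itgbl1 (4.18) and Dcn (3.93), decorin, completed them. Ttr was at least 11100-fold lower than the old wild-type mean of 1340 ± 1140 CPM, since its level in knockout was under 3 counts over the group. Old wild-type replicate 3 alone held 70.7 CPM, so the fold against that library is far smaller. Further falls were in Kl (-7.25), Slc4a5 (-5.62), Enpp2 (-5.46), Vat1l (-5.07), Clic6 (-4.84), Nsg2 (-4.12), Cldn2 (-4.07), Il1b and Slc13a4 (-3.47). Several of these, among them Kl, Enpp2, Clic6 and Cldn2, are transcripts of choroid plexus, and 13 of 23 genes of a choroid plexus list were lower in knockout. That list, too, was written after the leading genes had been seen. Of a tendon list, 19 of 24 genes were higher. Kera, Angptl7, Tnmd, Comp and Fmod were highest in old knockout replicates 2 and 3, the 2 male libraries, and without both their changes were 3.58, 2.59, 2.40, 2.27 and 1.85 and did not pass.

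Of 39 differentiation genes 1 rose, 8 fell and 30 did not pass (camera 6.38e-05, adjusted p = 0.602 with an estimated correlation), and the same numbers, 1 and 8, passed when adjusted over the list alone. Old knockout replicate 1 (list mean 7.32) lay within old wild type (7.18 to 7.41), replicates 2 and 3 lay at 6.28 and 6.51, and the list's median of -0.36 was -0.86 without replicate 1 and -0.17 without replicate 2. The mature myofibre list was lower by camera (0.00405, adjusted p = 0.649 with an estimated correlation) with 0 of 24 genes past the threshold. That direction is not stable: the median of -0.27 was 0.13 without old knockout replicate 2 (camera 0.992), 0.00153 without replicate 3, -1.48 without replicate 1, -0.18 without old wild-type replicate 2 and 0.79 without both male libraries, and replicate 1 (5.51) lay above every old wild-type library (4.59 to 5.01). In the TGF-beta and BMP list 12 of 54 genes rose and 2 fell (14 and 2 adjusted over the list alone), among them the receptors Tgfbr1 (1.04), Bmpr1a (0.80) and Acvr2a (0.76), which were 0.59, 0.37 and 0.24 with GC offsets, where Acvr2a did not pass, with a camera adjusted p of 0.0101 (adjusted p = 0.552 with an estimated correlation). The extracellular matrix list had 9 higher, including Matn2 (0.94), and 1 lower, Col5a3 (-0.88), of 45 (camera 0.00224, adjusted p = 0.547 with an estimated correlation). In the histone list 7 of 54 rose and 2 fell (camera 0.0101, adjusted p = 0.828 with an estimated correlation; 0.312 without old wild-type replicate 2 and 0.406 without old knockout replicate 2, and a median of 0.43 instead of 0.25 without old wild-type replicate 3), and in the cell cycle list 4 of 39 rose, Mcm4 (0.81), Bub1 (1.19), Ccnb1 (1.14) and Mki67 (0.68) (camera 0.103). The other Hox clusters had 3 lower of 11, Hoxc11, Hoxc8 (-1.57) and Hoxc6 (-0.96), and the Hoxa list 1 of 10, Hoxa9 itself (camera 0.0265 for each, adjusted p = 0.533 for each with an estimated correlation). Fry gave adjusted p-values of 0.0189 for the other Hox clusters and 0.0034 for the Hoxa list. In the senescence list 7 rose and 10 fell of 46, with the cell cycle inhibitor Cdkn1a (-1.05) and its activator Trp53 (-1.28) lower and Rb1 (1.04) higher. Bcl9 (-1.47) and Dvl2 (-0.81) of the Wnt list fell, where 6 rose and 8 fell of 54. Among 53 JAK-STAT genes 10 rose, including Spred1 (0.94) and Lepr (1.57), and 1 fell.

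Macrophage markers had 6 lower and 0 higher of 25, including Cd68 (-2.11) and Fcer1g (-2.97) (7 adjusted over the list alone, camera 8.57e-10, adjusted p = 0.533 with an estimated correlation). Fibroblast markers had 5 higher of 23 (camera 0.0031, adjusted p = 0.533 with an estimated correlation) and pericyte markers 4 of 17, such as Steap4 (1.49) (camera 0.0101, adjusted p = 0.649 with an estimated correlation). Neutrophil markers had 3 higher of 8, Mpo, S100a8 and Camp (camera 0.0777). Without old knockout replicate 1 the TGF-beta and pericyte lists no longer passed camera (0.0573 and 0.0559), and the matrix median of 0.38 was 0.57, or 0.24 without replicate 2. These counts depended on how the libraries' GC content was treated: with GC offsets 1002 genes passed, 552 higher and 450 lower, and 760 of the 2265 remained. Of 95 genes past the threshold that the naming rule covers, 33 did not pass with GC offsets, 89 without the males, 94 without the 2 doubted libraries and 19 to 44 without 1 library. Leaving out the 2 male libraries, which leaves 1 old knockout library, gave 121 genes and a median of 0.12 for the differentiation list, leaving out the 2 libraries with many reads outside genes gave 3, and scaling by library size alone gave 359 higher and 1827 lower and by upper quartile 1021 higher and 1268 lower.

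Knockout in young mice was set against young wild type, and 10 of 39 cell cycle genes and 8 of 54 histone genes were lower. Plk1, a mitotic kinase, fell from 20.8 ± 3.67 to 5.83 ± 2.04 CPM (log2 fold change -1.78 ± 0.29, adjusted p = 0.00168), and E2f1, a regulator of S phase entry, fell by 1.46. Pax7 fell from 366 ± 31.9 to 232 ± 15.3 CPM (-0.66 ± 0.14, adjusted p = 0.00568), although its change was -0.33 with GC offsets and -0.39 with GC and length offsets and then did not pass, and Heyl fell by 1.21. Of the 27 satellite identity genes 1 rose, 5 fell and 21 did not pass, 16 had positive values (median 0.13), and camera gave 0.509. In all, 2831 of 13540 genes changed (20.9%), 1477 higher and 1354 lower. A list count in 1 direction stands against the number of that direction among the 13540, and not against 20.9%. The largest changes again included Lars2 (6.12), Angptl7 (4.30), Zfp709 (2.70), Omd (2.64), a proteoglycan of bone and tendon, and Cldn4 (2.50) higher, and Kl (-6.96), Clic6 (-5.90), Enpp2 (-5.84) and Slc4a5 (-5.07) lower. Ttr was at least 19900-fold lower than the young wild-type mean of 2510 ± 1600 CPM, with 14 of 23 choroid plexus genes lower.

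Of 39 cell cycle genes 0 rose and 10 fell (18 adjusted over the list alone), including Ube2c (-1.09) and Ccne1 (-0.95), with a median of -0.49 and a camera adjusted p of 0.00068 (adjusted p = 0.809 with an estimated correlation). Of 54 histone genes 8 fell, such as Hist1h1b (-0.82) (7 adjusted over the list alone, camera 0.00068, adjusted p = 0.809 with an estimated correlation). Respiratory chain genes had 2 higher and 7 lower of 61, Cyc1 (-0.74) and Ndufa8 (-0.75) among them, and matrix genes 1 higher and 9 lower of 45, such as Eln (-2.65), elastin, and Sparc (-0.87) (camera 0.0217 for each, adjusted p = 0.809 for each with an estimated correlation). The mature myofibre list had 2 lower of 24, Eno3 (-1.10) and Actn3 (-0.83) (camera 0.0456, adjusted p = 0.809 with an estimated correlation). In the differentiation list 4 of 39 fell, Mef2d (-1.03), Tnnt1 (-0.86) and the acetylcholine receptor subunits Chrnd (-1.42) and Chrng (-1.53) (camera 0.104). The TGF-beta list had 6 higher, Tgfbr1 (1.13, or 0.54 in the lowest of the alternatives) first among them, and 3 lower. None of 25 macrophage markers passed. The histone list did not pass camera without young knockout replicate 1 (0.0984; median -0.22 instead of -0.52 without young wild-type replicate 2). Nor did the matrix list without young wild-type replicate 1 or young knockout replicate 3 (0.262 and 0.0823), or the myofibre list without young wild-type replicates 1 or 2 or young knockout replicate 3 (0.0651, 0.147 and 0.0512). The respiratory chain list passed without young wild-type replicate 1 (median -0.38 instead of -0.25) or young knockout replicate 2 and did not pass without any of the other 4 libraries (0.0508 to 0.276). GC offsets left 773 genes, 380 higher and 393 lower, and 570 of the 2831 remained, and 41 of 82 genes under the naming rule did not pass while 1 reversed (6 to 22 did not pass without 1 library). Of the 5 lists past camera only the cell cycle list still passed. Library size alone gave 865 higher and 1278 lower, and a fit of the 2 groups alone gave 1536.

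Ageing in knockout changed 2 genes past the threshold, both higher in old mice, while scaling by library size alone called 2 others, both lower. Eno3, the muscle enolase, rose from 66.8 ± 14 to 201 ± 30.3 CPM (log2 fold change 1.58 ± 0.22, adjusted p = 0.0368), and Klhl30 rose from 17.1 ± 1.5 to 40.9 ± 8.27 CPM (1.26 ± 0.17, adjusted p = 0.0368). With the trimmed-mean factors and filter used here edgeR called 0 lower, while 1316 genes had an unadjusted p under 0.05, edgeR without a filter called 19 higher and 19 lower and with 1 surrogate variable 6 higher and 1 lower, DESeq2 called 67 higher and 69 lower, and limma-voom called 0. Genes with the smallest p-values that did not pass included Tpm1 (1.14), Got1 (1.09) and Wdfy1 (1.63) among the higher, and Ctnna2 (-2.15), Igfbp3 (-1.10), Ephb1 (-0.97), Gpc3 (-1.31) and Pik3ip1 (-0.89) among the lower, with adjusted p-values of 0.0546 to 0.0652. Of 39 cell cycle genes, 38 had positive values, with 0 past over all genes and 16 when adjusted over the list alone (median 0.54, camera 1.79e-19, adjusted p = 0.312 with an estimated correlation). All 54 histone genes had positive values, with 0 past (median 0.53, camera 2.91e-19, adjusted p = 0.393 with an estimated correlation). The respiratory chain list was higher (median 0.24, camera 2.86e-08, adjusted p = 0.606 with an estimated correlation). In the lowest of the alternatives the medians of the cell cycle, histone and respiratory chain lists were 0.27, 0.32 and 0.11. Neutrophil and erythroid markers had camera adjusted p-values of 4.68e-05 and 0.00548 upward (adjusted p = 0.312 and 0.393 with an estimated correlation) and macrophage markers 0.000517 downward (adjusted p = 0.606 with an estimated correlation). Without young knockout replicate 1 the macrophage median of -1.27 turned to 0.77, with -0.82 and -2.21 without old knockout replicates 2 and 3. The neutrophil median of 3.43 was 1.82 without old knockout replicate 3, and the erythroid list did not pass without old knockout replicate 1 (0.0641) or young knockout replicate 1 (0.086). Satellite identity, Notch, Trithorax and Polycomb and immediate early lists were lower by camera (0.00266, 0.0216, 0.0168 and 0.00941, adjusted p = 0.312, 0.312, 0.312 and 0.638 with an estimated correlation). The fibroblast list was higher (0.0123, adjusted p = 0.586 with an estimated correlation). So was the mature myofibre list (0.02, adjusted p = 0.638 with an estimated correlation), with Eno3 past the threshold. The myofibre median of 0.54 turned to -0.23 without old knockout replicate 1 (camera 0.233; list mean 5.51 there against 3.23 and 3.79 in replicates 2 and 3) and was 0.93 without replicate 2, and the list did not pass without young knockout replicates 2 or 3 (0.0788 and 0.0943). The differentiation list was lower by camera with a median of -0.23 and a mean of 0.01, and the Schwann and neural list higher with a median of -0.01 (-0.27 without young knockout replicate 1, 1.26 without young knockout replicate 3) and a mean of 0.07 (0.02 and 0.00517, adjusted p = 0.638 and 0.606 with an estimated correlation). Other lists also hung on single knockout libraries. The immediate early median of -0.35 turned to 0.29 without young replicate 3, and the list did not pass without old replicate 2 (0.259). The fibroblast list did not pass without old replicate 3 (0.0551) or young replicate 1 (0.626) and had a median of 0.76 instead of 0.34 without young replicate 3. The Trithorax and Polycomb list did not pass without old replicate 3 or young replicate 1 (0.0514 and 0.169). The Notch list did not pass without old replicate 2 or young replicates 1 or 3 (0.0519, 0.086 and 0.0602). The differentiation list passed only without old replicate 1 or young replicate 3, and the Schwann list only without old replicates 2 or 3 or young replicate 3. The satellite identity median of -0.24 was -0.09 without old replicate 2 or young replicate 3, the respiratory chain median was 0.14 without young replicate 1, and the histone median was 0.82 without young replicate 2. The old knockout group holds 2 male libraries and the young one none, so sex is mixed into this comparison and the interaction. Leaving out old knockout replicate 1 gave 102 genes, and leaving out old knockout replicate 2 gave 0.

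The age effect differed between genotypes past the threshold for 2 genes. Il1b rose with age in wild type and stood at 2.34 ± 1.92 CPM in young and 0.769 ± 0.203 CPM in old knockout, with an interaction of -5.15 ± 0.71 on the log2 scale (adjusted p = 0.0339). Ndn, the growth suppressor necdin, stood at 14.9 ± 0.765 and 4.78 ± 0.193 CPM in young and old wild type, and at 11.4 ± 2.44 and 21 ± 5.19 CPM in young and old knockout (interaction 2.54 ± 0.30, adjusted p = 0.0131). The next genes did not pass: Matn2 (0.96), Tril (1.65), Adamts4 (1.04) and Vasn (0.78) upward, with adjusted p-values of 0.242 to 0.264, and Zfp82 (-2.23), Pik3ip1 (-1.18), Slc7a11 (-3.24) and G530011O06Rik (-1.93) downward, with 0.119 to 0.235. Extracellular matrix genes had positive interactions in 43 of 45 cases (median 0.77), with 0 past over all genes and 13 when adjusted over the list alone (camera 1.27e-14, adjusted p = 0.30 with an estimated correlation). The matrix median was 0.31 in the lowest of the alternatives. Macrophage markers were negative in all 25 (median -3.13), with 0 past and 5 when adjusted over the list alone (camera 2.05e-16, adjusted p = 0.30 with an estimated correlation). Without young knockout replicate 1, whose list mean was 3.26 against 0.523 and -0.479 in replicates 2 and 3, the median was -0.83. The Il1b interaction has the direction of this list, and whether it arises within satellite cells was not tested. DESeq2 called 60 genes. Leaving out single libraries gave 0 to 116 genes, the highest without young knockout replicate 3.

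The fold changes of the comparisons were set against each other for 3 pairs. Ageing in wild type and knockout in old mice share the old wild-type libraries with opposite signs, so their fold changes correlate negatively with no effect present. Pearson's r across 13540 genes was -0.37 (Spearman's rho -0.27), against a mean of -0.47 in 20 simulations with no group changed and -0.27 (lowest -0.30) with ageing as fitted and no knockout effect, where 732 genes were called for ageing on average against 144 in the data, so that its ageing effects are too large. In 20 further simulations both effects were present and unrelated, scaled for their errors, with 150 genes called for ageing and 2374 for knockout on average. There r averaged -0.22 (lowest -0.25), rho -0.20 (lowest -0.21) and the covariance -0.10 (lowest -0.11), so r, rho and the covariance of the data (-0.16) were more negative than in each of these simulations. The jackknife spread of r over libraries was 0.124. In all these simulations genes were drawn independently of each other, without the trends over many genes that the libraries hold. Values outside the simulated range therefore do not show that the 2 effects are related. Of the 144 genes changed with age, 103 had the opposite sign in knockout against wild type in old mice (71.5%). In the simulations with unrelated effects that share was 60.5% to 78.2%. Of those 103, 44 passed the threshold in both comparisons, against 13 to 51 in the simulations. The share of opposite signs and the count of 44 thus lie within the simulated ranges, unlike r, rho and the covariance. These simulations called 110 to 204 genes for ageing, however, so the count is not like for like. As a share of the genes called for ageing, such genes made up 11.5% to 29.0% there. The 44 of 144 in the data lie above that range. In knockout against wild type in young mice, 31 of the 35 genes raised with age and 91 of the 109 lowered had the sign of ageing. That comparison shares the young wild-type libraries with ageing in wild type, with equal signs, which alone gives that direction. It was not simulated. With 3 old wild-type libraries the controls cannot be split into parts of 2 or more. The knockout comparisons in old and young mice share no library. Their fold changes had r = 0.57 (rho 0.57), with 780 genes higher in both and 504 lower in both, against 141 and 97.6 for independent lists, and both follow the GC difference between the genotypes. With GC offsets r was 0.50, with 154 higher and 141 lower in both. Ageing in wild type and ageing in knockout had r = 0.03 (rho 0.09), and 105 of the 144 genes had the same sign. Genes are not independent replicates in any of these values.

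**Figure D4:**
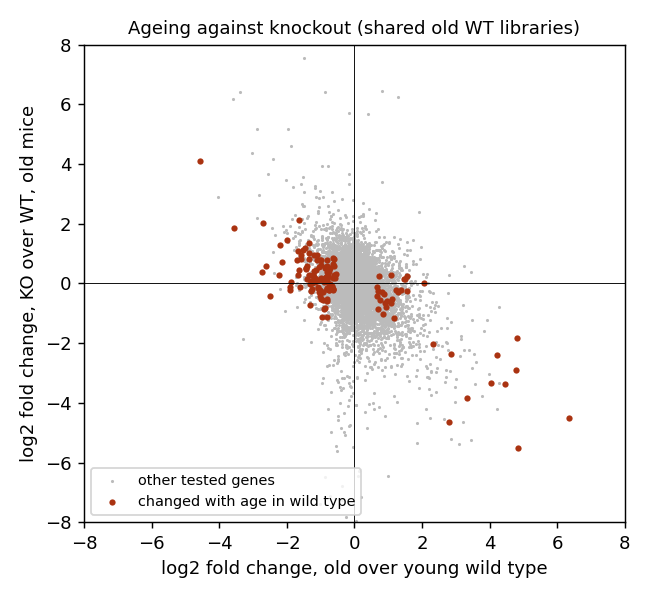
Log2 fold change of old over young wild type (horizontal axis) against knockout over wild type in old mice (vertical axis), 1 point per tested gene, with the genes changed with age in wild type in red; 6 genes lie outside the axes. The red points lie mostly in the upper left and lower right, as 103 of 144 have opposite signs, and the shared old wild-type libraries alone give that direction.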

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

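All tests of explanations in this part were chosen after the results they address had been seen. The first group of results stands out because the age effect differed between genotypes in the interaction test. The genes were Il1b (-5.15 on the log2 scale) and Ndn (2.54). Of the lists, 15 passed camera with the preset correlation and 0 with an estimated one. Their median interactions were 4.15 for neutrophil, 1.71 for erythroid, 0.86 for pericyte, 0.77 for extracellular matrix, 0.71 for histone, 0.70 for fibroblast, 0.62 for cell cycle, 0.50 for Schwann and neural, 0.27 for immediate early, 0.20 for respiratory chain, 0.17 for Wnt and 0.13 for TGF-beta genes. They were -0.12 for differentiation, -0.43 for Hoxa and -3.13 for macrophage genes.

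Single libraries moved many of these medians. Without young knockout replicate 1 they were -0.83 for macrophage, -0.0556 for immediate early, -0.00785 for Schwann and neural, 0.38 for fibroblast and 0.12 for respiratory chain genes. Without young knockout replicate 3 they were 1.61 for Schwann and neural, 1.52 for pericyte, 1.37 for fibroblast, 0.96 for immediate early, 0.44 for TGF-beta and 0.40 for cell cycle genes. Without young knockout replicate 2 they were 0.08 for Schwann and neural, 0.05 for immediate early, 0.08 for Wnt and 0.01 for TGF-beta genes. Without old knockout replicate 1 they were -0.72 for differentiation, -0.04 for TGF-beta, 0.05 for immediate early, 0.08 for Wnt and 0.16 for Schwann and neural genes, and without replicate 3 0.02 for differentiation, 0.02 for TGF-beta, 0.44 for fibroblast and 2.68 for neutrophil genes. Over all 12 omissions the differentiation list ran from -0.72 to 0.02, the TGF-beta list from -0.04 to 0.44 and the respiratory chain list from 0.10 (without young wild-type replicate 2) to 0.33 (without young wild-type replicate 1). The Hoxa list stayed past camera in 4 of the 12, the erythroid list in 7, the differentiation list in 6, the immediate early and TGF-beta lists in 7 and 8, the Wnt and respiratory chain lists in 9 each and the Schwann and neural list in 10.

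A second group comes from reads that no gene comparison used. Per gene read, reads outside genes numbered 2.46 in old knockout replicate 3, above every wild-type library, and 0.657, 1.36 and 0.703 in old wild-type replicates 1, 2 and 3, each above every young wild-type library. Reads with several alignments numbered 7.54 per gene read in old knockout replicate 3 and 3.49 in young knockout replicate 2, above every wild-type library. No group has more than 3 libraries, so single libraries were not tested for standing apart.

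Other groupings of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 144 genes for ageing in wild type, 2265 for knockout in old mice and 2831 for knockout in young mice, 1 of 10 splits in each case, and the highest other split gave 0. For ageing in knockout the real split gave 2 genes, 3 of 10 splits gave as many, and the highest other gave 379. That split set old replicates 1 and 3 with young replicate 3 against the rest, which points to a structure of the knockout samples other than age. For the interaction 7 of 100 drawn splits, the real one included, gave 2 genes or more, with a highest other of 234. That split, and those with 155 and 164 genes, kept the real ages of the wild-type libraries and regrouped only the knockout libraries. Such splits hold the wild-type age effect, so the share of 7 in 100 does not measure chance alone. Chance was therefore not excluded, and the splits cannot decide it.

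The differences between knockout and wild type go with a difference between libraries. The GC trend that the offsets remove is argued against as the whole cause by the calls that passed with them, 33.6% in old and 20.1% in young mice, although most calls ended there. A trend left over by the offsets was not tested. Scaling driven by Lars2 and other dominant genes is argued against too, since 97.5% of the calls in old mice were kept with factors computed without the 50 most abundant genes. The sex of 2 old knockout animals is argued against for the 1284 genes that passed in the same direction in young mice (238 for independent lists), where no library has male levels of Y-linked reads. For the other 981 it stays open, since leaving out the 2 males leaves 1 old knockout library, too few to decide for either part. A library batch that follows genotype stays open, since batch and genotype cannot be told apart (of 16 choroid plexus list genes not seen before the list was written 5 passed in both knockout comparisons, against 1.52 by chance, among them Rdh5, at 15.2 to 23 CPM in knockout), and so does the loss of Hoxa9, untested.

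All 25 macrophage markers had positive values in old over young wild type, but 0 passed over all genes and the list did not pass camera with an estimated correlation (adjusted p = 0.314). Background reads in old replicate 2 are argued against, since the list's median was 1.74 without that library. More macrophage RNA in the sorted fraction may account for these values. Outside the list, 25 macrophage genes, many of them shared with other leukocytes, had a median change of 1.93 (bootstrap SE over genes 0.24). Of these, 23 were positive and 0 passed the threshold. That SE measures the spread between genes, which are not independent replicates, and not the spread between libraries. The 5 most abundant markers, Lyz2, Gpnmb, Cd14, Ctss and Mpeg1, stood at 18.6 to 47.3 CPM in old wild type (adjusted p = 0.0665 to 0.463), and the isolation of satellite cells would be meant to remove macrophages. A change of these genes within satellite cells with age was not tested and stays open.

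In old wild type 12 of 45 extracellular matrix genes were lower and 33 did not pass, and the list did not pass camera with an estimated correlation (adjusted p = 0.163). The list passed fry (adjusted p = 0.0084). Background reads in old replicate 2 are argued against by a median of -0.66 without it, and the GC trend by a median of -0.68 with GC offsets. Fewer fibroblasts in the sorted fraction could not be told apart from a change within satellite cells. The 18 fibroblast markers outside the matrix list had a median of -0.39, against -0.69 for the matrix list. Its bootstrap SE of 0.253 was drawn over genes and not over libraries. An effect of age on the satellite cells stays open, untested.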

How the results depend on the processing

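The offsets for GC content and length and the fits without the 2 male or the 2 doubted libraries (old wild-type replicate 2 and old knockout replicate 3) were chosen after seeing the data. Correlations of deviations from the group means ran from -0.26 to 0.23 over 18 same-numbered pairs of libraries, and 3 exceeded 0.1. Pairs with different numbers were not set beside them, so whether the replicate numbers pair the samples stays open. With the replicate block 79 genes passed for ageing in wild type and 0 for ageing in knockout, and the other 3 counts stayed within 1.5 times. The rule for repeated libraries did not apply. No cause of the changes below was tested, except that omissions leave fewer samples.

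Ageing in wild type (144) gave 460 genes with DESeq2, 350 with limma-voom, 1026 with sample weights, 83 with library size alone, 913 with only 2 groups, 2 without the doubted libraries, 78 with a 2-fold minimum and 6 to 73 without single libraries. Knockout in old mice (2265) gave 4270 with sample weights, 1002 with GC and 1346 with GC and length offsets, 121 without male and 3 without doubted libraries, 631 with a 2-fold minimum and 779 (without old knockout replicate 3) to 1695. Knockout in young mice (2831) gave 1536 with only 2 groups, 773 and 1014 with the offsets, 706 with a 2-fold minimum and 1479 (without young wild-type replicate 2) to 3140. Ageing in knockout (2) gave 136 with DESeq2, 0 with limma-voom, 22 with sample weights, 0 with upper-quartile factors, 38 without a filter, 0 with only 2 groups, 7 with a surrogate variable, 17 with GC and length offsets, 15 without male and 1 without doubted libraries, and 0 to 102. The interaction (2) gave 60 with DESeq2, 1 with limma-voom, 4 with library size alone, 6 without a filter, 1 with GC and length offsets, 0 without male and 0 without doubted libraries, and 0 to 116. Library size alone moved the median of all genes by -0.25 in knockout against wild type in old mice and by -0.16 in the interaction.

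An estimated correlation left 0 lists in each of the 5 comparisons. Fry left 4 for ageing in wild type, the extracellular matrix, satellite identity and Notch lists lower and the Hoxa list higher (0.0384). For knockout in old mice it left 3, all lower, namely Hoxa, other Hox, and Trithorax and Polycomb (0.0265), and it left 0 in the others. Without a filter 16 lists passed for knockout in old mice and 13 in young mice, where GC offsets left 2. Single omissions gave 11 to 15, 9 to 13, 3 to 8, 7 to 14 and 8 to 17 lists in the 5 comparisons. Hoxa9 in old mice kept its sign, at -1.44 without male and -1.76 without doubted libraries, where it no longer passed, and -1.75 to -1.41 without single libraries. The correlation of ageing with knockout was -0.70 without a filter, -0.81 over the genes changed with age and -0.43 to -0.31 without single libraries. Signs of medians reversed without the male libraries for the mature myofibre (0.79) and differentiation (0.12) lists in knockout against wild type in old mice. The differentiation median also reversed with age in knockout (0.14) and in the interaction (0.0893). With GC offsets Numbl in young mice reversed (0.00479, or 0.0288 with length), and with length offsets so did Klf6 (-0.0041). Without single libraries the mature myofibre list with age in knockout ran from -0.23 to 0.93, the immediate early list from -0.66 to 0.29, the macrophage list from -2.21 to 0.77 and the immediate early list in the interaction from -0.0556 to 0.963. Hoxa9 with age in knockout reached 0.0015 without old knockout replicate 2.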

Other observations

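The tests in this part, and both lists in it, were chosen after the leading genes had been seen. Tendon genes were higher in old knockout than in old wild type for 19 of 24 list members, with a median of 2.78, and in young mice 4 were higher and 1 lower, with a median of 1.51. With age in wild type none of the 24 passed, and 20 had negative values. Of the 15 list members not seen before the list was written, 10 were higher in old knockout. Scx, a transcription factor of the tendon lineage, was at -0.03 in old mice (adjusted p = 0.946) and was the 1 gene lower in young knockout (-0.85, adjusted p = 0.0333), and Mkx, Tnc, Prelp and Col14a1 did not pass in old mice. Some members were highest in old knockout replicates 2 and 3, the 2 male libraries, though others, such as Ogn, were not: Tnmd stood at 15.7 and 45.9 CPM there against 3.00 CPM in replicate 1, Comp at 69.5 and 81.4 CPM against 6.91 CPM, and Ogn at 160 and 300 CPM against 365 CPM. Sex is thus mixed into the size of this change. Tendon cell RNA in the old knockout libraries may account for the genes that rose, though not for Scx, and the isolation of satellite cells would be meant to remove such cells. Dcn also stands in the fibroblast and matrix lists.

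The wild-type libraries held choroid plexus transcripts in amounts that varied 60.3-fold for Ttr. If a single source of such RNA had been added in varying amounts, its genes would keep 1 ratio to Ttr. For 10 other choroid plexus genes the coefficient of variation of that ratio had a median of 0.373 over 6 wild-type libraries, against 0.649 for the levels. The median lay 0.0484 above 0.5 of the latter, with a bootstrap SE over genes, not libraries, of 0.0941. For 4 of the 10 genes the ratio's coefficient of variation was under 0.5 of that of their own level (Enpp2 0.131 against 0.691, Kl 0.229 against 0.637, Otx2 0.283 against 0.649, Kcne2 0.335 against 0.868), so the test decides nothing. Some of the others, such as Folr1 at 1.29 CPM in old wild-type replicate 3, reach knockout levels (up to 1.5 CPM). The source of these reads stays open.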
